A study of Mus musculus with 8 samples.

How the data were processed

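RNA of adherent ASZ001 cells was extracted with RNeasy columns and made into TruSeq RNA libraries read on an Illumina HiSeq instrument, per the labels. The 8 libraries form a design of 2 shRNAs by 2 treatments, with 2 libraries in each of 4 groups: non-silencing shRNA with DMSO, Tgfbr1 shRNA with DMSO, and both shRNAs with Dox and 4OHT in the libraries labelled RasV12. Culture conditions, doses and times are not given in the sources used here, and neither is the origin of the 2 libraries of a group.

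The authors deposited 1 table of estimated counts per gene, not normalized, which the authors made by alignment with TopHat and counting with HOMER, per the submitters' processing notes. It holds 24909 entries by 8 libraries, and 100% of its values were multiples of 0.5. Per the labels and the submitters' processing notes, this was done at the level of isoforms on the mouse build mm9, and DESeq2 is also named. Versions, the strand setting, the treatment of reads that match several genes and any filter are not given in the sources used here. Reads of near-identical genes (Krt6a and Krt6b, Krt14, Krt16 and Krt17, the Sprr genes, Oaz1 and Hmga1 with their copies) may therefore be divided or counted in more than 1 of them, and reads of overlapping genes cannot be told apart. Symbols were used as deposited. In 26 entries the symbol reads as a date, and none of these is named in the text. Where 2 entries had the same symbol the one with more counts was kept, which dropped 2 and left 24907 symbols. Each column was matched to a sample by its name. The design of the tests had assumed whole counts; as the values proved to be expected counts, they were rounded to whole numbers for the tests.

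Library totals were 16233379 and 14130153.5 counts in the NS libraries under DMSO and 12874759 and 14195384.5 in the knockdown libraries under DMSO. They were 12724604.5 and 13590485 in the NS libraries under Dox and 4OHT and 15542242 and 13047710 in the knockdown libraries under Dox and 4OHT. Intervals and the floor of 3 counts cover counting error only. Where a group held no counts of a gene, the fold was computed against 3 counts over the group, and with 1 to 3 counts a ratio was given with its 95% interval, from the exact binomial interval of the counts.

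Genes were tested with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr at its default settings kept 12538 genes, with 99.96% of all counts, and left out 12369. TMM factors scaled the libraries, and all 8 libraries entered 1 model with a mean per group (4 residual degrees of freedom). The quasi-likelihood F test with robust estimation was applied to 5 contrasts. These are Dox and 4OHT against DMSO in NS cells, the same in knockdown cells, knockdown against NS cells under DMSO, the same under Dox and 4OHT, and the interaction. Calls are at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested, two-sided. The biological coefficient of variation was 3.37%. CPM were taken with the TMM factors, means and SDs over the 2 libraries. Standard errors of log2 changes are those of the fitted model.

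Gene lists were tested with camera in limma 3.58.1, with a correlation of 0.01 between genes, for lists with at least 3 tested members, adjusted over the lists of a comparison. The 26 lists were chosen before the data were examined, as were the design of the tests, the rule for named genes and the alternatives except those said to be added later. They hold MAPK output and feedback, AP-1 subunits, EGFR family ligands, Hedgehog targets, basal keratinocyte genes, hair follicle and basal cell carcinoma epithelium, squamous terminal differentiation, wound and squamous carcinoma keratins and alarmins and simple epithelial keratins. Further lists are TGF-beta and SMAD targets, TGF-beta family receptors and SMADs, BMP targets, mesenchymal genes, proteases and invasion, proliferation and p53 targets and senescence. The others are inflammatory cytokines and NF-kB, interferon-stimulated genes, hypoxia and glycolysis, ATF4 and the integrated stress response, sterol biosynthesis, YAP and TEAD targets, Wnt targets, the Notch pathway, and markers of fibroblasts and of immune, endothelial and pigment cells. Of their members 2 were not found under their symbols. The simple epithelial keratins had too few tested members for the list test.

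The genes named were chosen by a fixed rule. Tgfbr1, Hras and Nras are always named. For each comparison the rule takes the 7 genes with the largest rise and the 7 with the largest fall (5 and 5 for the interaction) that passed the test, had a mean of at least 5 CPM in the groups compared and no overlap between libraries of the groups, predicted genes and small RNAs left out. It also takes up to 3 members with the smallest p of each list with at least 2 members past the test, and otherwise the member past the test or the 2 most abundant. Esr1 is named by this rule. Genes outside it, which are Gli1 and some among the closing observations, were chosen after their values were seen. The text names part of the genes that the rule takes. Among those left out are 2 genes whose single results are not reported here, whatever their values.

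The scripts were tested on simulated counts with the means and library sizes of the data, in which 200 genes were changed, 50 at each of 4 folds. At 1.25-fold, 1.5-fold, 2-fold and 4-fold, 29, 39, 46 and 50 of 50 were recovered for Ras in NS cells (12351 genes tested). The numbers were 25, 44, 46 and 49 for the knockdown under DMSO (12361 genes), and 27, 41, 46 and 50 for Ras in knockdown cells (12339 genes). They were 29, 38, 47 and 49 for the knockdown under Dox and 4OHT (12327 genes) and 15, 31, 43 and 47 for the interaction (12346 genes). Of the calls 9.89%, 7.87%, 3.53%, 10.9% and 3.55% were false in the same order. With the proliferation list shifted by 0.5 on the log2 scale, camera called it and 2 of the other 24 lists.

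Alternatives were RLE and upper quartile factors, no filter on low counts, a filter of 1 CPM in 2 libraries, the sum of entries of 1 symbol, only the 4 libraries compared, DESeq2 1.42.0, an adjusted p of 0.01, a fold of at least 2, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Removal of a trend with gene length, the counts without Rn45s, and the extension of some of these settings to lists, overlaps and named genes were added after seeing the data. With a library left out the filter was applied anew with a group of 1 library, so more genes and list members could be tested. The 2 fits without an NS DMSO library had 12685 genes in common, against 12538 in the main fit. For the neighbours of Hras, the order of genes came from the GRCm38 annotation, in which 12269 (97.9%) of the tested symbols were found; as this is not the build of the table, no coordinates are given. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.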

Results

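Messenger RNA was measured in 8 libraries of ASZ001 cells, a mouse basal cell carcinoma line. The cells carried either a non-silencing shRNA (NS cells) or an shRNA against Tgfbr1, the type I receptor of TGF-beta (knockdown cells). They were treated with DMSO or with Dox and 4OHT, the usual short names of doxycycline and 4-hydroxytamoxifen. The libraries treated with Dox and 4OHT are those labelled RasV12, an activated form of Ras. Each of the 4 groups held 2 libraries, with totals from 12724604.5 to 16233379 counts. Of the genes listed, 12538 were tested. The title of the series places the work in the transition from basal to squamous cell carcinoma. No library received Dox and 4OHT without RasV12, so the effect of the drugs cannot be separated from that of Ras, and the term Ras response is used for both. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Replicates had correlations of 0.995 to 0.996 across genes on the log scale, genes not being independent replicates. Their counts differed by more than sampling noise in every group, so none was taken as a second reading of the same library. This does not exclude 2 libraries made from 1 culture. The first principal component held 66.9% of the variance and the second 16.5%. Reads of the ribosomal RNA gene Rn45s took 2.49% and 2.57% of the counts in the knockdown libraries under Dox and 4OHT and 0.916% and 2.76% in the NS libraries under Dox and 4OHT. They took 0.387% and 1.36% in the knockdown libraries under DMSO and 0.816% and 0.549% in the NS libraries under DMSO.

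Tgfbr1, the targeted gene, was measured at 77.1 and 80.4 CPM (counts scaled to the size of the library) in the NS libraries under DMSO and at 10.2 and 8.08 CPM in the knockdown libraries under DMSO. Under Dox and 4OHT it was at 104 and 91.6 CPM in NS cells and at 8.86 and 9.38 CPM in knockdown cells. Its log2 change with the knockdown was -3.11 ± 0.09 (SE) under DMSO (adjusted p = 1.72e-19) and -3.43 ± 0.09 under Dox and 4OHT (adjusted p = 1.83e-20). Every adjusted p of a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested. All 8 libraries matched their labels for the shRNA. In NS cells Tgfbr1 rose with Ras by 0.32 ± 0.06 on the log2 scale (adjusted p = 0.000141), whereas in knockdown cells its change was 0.00 ± 0.14 (adjusted p = 0.99). The difference between these responses was -0.31 ± 0.15 (adjusted p = 0.118) and passed without knockdown DMSO replicate 2 (-0.48, adjusted p = 0.0384) or NS Dox-4OHT replicate 2 (-0.41, adjusted p = 0.03). Transcripts of a RasV12 transgene were not analysed separately here. Hras, a Ras gene, was at 176 and 179 CPM in NS cells under DMSO and 162 and 158 CPM in NS cells under Dox and 4OHT. It was at 57.9 and 58.6 CPM in knockdown cells under DMSO and 53.3 and 52.4 CPM in knockdown cells under Dox and 4OHT. It was thus lower in knockdown than in NS cells under both treatments, with log2 changes of -1.61 ± 0.04 (adjusted p = 2.35e-21) and -1.60 ± 0.05 (adjusted p = 6.18e-21). Nras was higher in knockdown cells under both treatments, by 0.55 ± 0.03 (adjusted p = 1.39e-13) and 0.42 ± 0.03 (adjusted p = 3.6e-11). With Ras, Hras changed by -0.15 ± 0.04 in NS cells (adjusted p = 0.00324; 0.0804 by DESeq2) and by -0.14 ± 0.05 in knockdown cells (adjusted p = 0.0364). The latter no longer passed when each of the 4 knockdown libraries was left out in turn (0.0596 and 0.14 without the DMSO replicates, 0.103 and 0.153 without the Dox-4OHT replicates). Nras changed with Ras by 0.08 ± 0.04 in NS cells (adjusted p = 0.0744) and -0.05 ± 0.03 in knockdown cells (adjusted p = 0.287). Esr1, the oestrogen receptor alpha gene, whose protein binds 4OHT, went from 15.9 and 14.1 CPM under DMSO to 3451 and 3657 CPM under Dox and 4OHT in NS cells. It went from 22.8 and 22.4 to 3987 and 3787 CPM in knockdown cells. These log2 changes were 7.88 ± 0.05 (adjusted p = 4.53e-30) and 7.43 ± 0.05 (adjusted p = 7.93e-30).

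**Figure D1:**
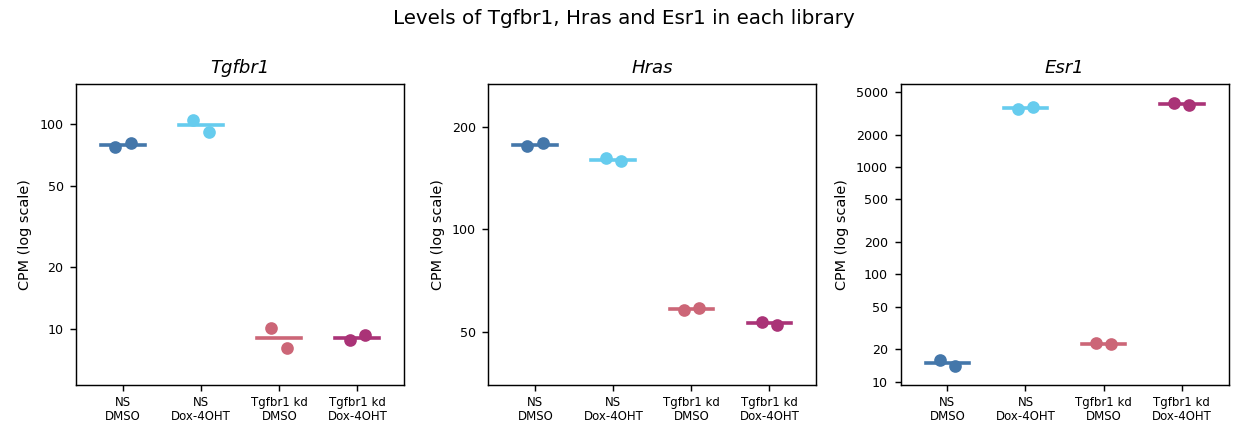
Levels of Tgfbr1, Hras and Esr1 in CPM on a log axis in the 4 groups, with 1 point per library and a line at the mean of the 2 libraries. Tgfbr1 lies between 8.08 and 10.2 CPM in the 4 knockdown libraries, Hras is lower in all 4 knockdown libraries, and Esr1 lies between 3451 and 3987 CPM in the 4 libraries that received Dox and 4OHT and between 14.1 and 22.8 CPM in the others.

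The first comparison, Dox and 4OHT against DMSO in NS cells, addresses what activated Ras changed in basal cell carcinoma cells with unsilenced Tgfbr1. The ETS family genes Etv4 and Etv5, which ERK signalling induces, rose from 11.2 ± 0.776 to 119 ± 7.20 CPM (mean ± SD, n = 2) and from 3.26 ± 0.213 to 61.6 ± 0.684 CPM. Dusp6, an ERK phosphatase that acts as a feedback inhibitor, rose by 2.77 ± 0.09 on the log2 scale (adjusted p = 3.24e-11). The EGFR ligand genes Epgn and Tgfa rose by 1.33 ± 0.10 and 0.81 ± 0.07. Keratins of the basal layer fell in the same cells: Krt14 went from 8462 ± 283 to 3605 ± 94.2 CPM and its partner Krt5 from 13238 ± 58.7 to 5859.5 ± 127 CPM.

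Of the 17 MAPK output and feedback genes, 15 rose and 1 fell with Ras in NS cells, and all 7 measured EGFR family ligands rose. Among the 10 AP-1 subunits 6 rose and 1 fell. Atf3, a stress-induced member, rose by 2.40 ± 0.09 and Fosl2 fell, with a log2 change of -0.61 ± 0.03. Of 23 proliferation genes 20 rose and 2 fell, among them the mitotic cyclin Ccnb1 at 0.51 ± 0.05 and the replication helicase subunit Mcm5 at 0.28 ± 0.04. Genes of hypoxia and glycolysis (11 of 15 rose, 2 fell) included Vegfa, the vascular growth factor, at 1.64 ± 0.09. Those of the ATF4 stress response (13 of 16 rose, 2 fell) included Atf4 at 0.76 ± 0.04 and Trib3 at 1.40 ± 0.09, while the cystine transporter gene Slc7a11 fell, with -1.32 ± 0.05. Basal keratinocyte markers went the other way: 9 of 13 fell and 3 rose. The laminin chain gene Lama3 fell, with -0.94 ± 0.03. Of the 6 tested wound and squamous carcinoma keratins and alarmins 4 fell and 1 rose, Krt16 changing by -2.73 ± 0.07 and Krt6a by -1.02 ± 0.04. Reads of Krt6a and Krt6b, and of Krt14, Krt16 and Krt17, may have been divided between these near-identical genes, so each such value is uncertain. Among 21 genes of squamous terminal differentiation 5 fell and 3 rose. Those that fell included Sbsn (-3.61 ± 0.13) and Dmkn (-2.03 ± 0.07), both encoding proteins secreted by suprabasal keratinocytes, and the transcription factor gene Klf4 (-0.37 ± 0.04). The YAP and TEAD targets counted 3 lower and 1 higher members of 9, with Amotl2 at -1.19 ± 0.05.

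Outside these lists, Gsta3, a glutathione transferase gene, fell from 31.0 ± 3.38 to 0.756 ± 0.241 CPM, the neuronal tubulin gene Tubb3 from 61.7 ± 4.02 to 6.73 ± 0.304 CPM, and the desmosomal cadherin gene Dsg1b from 13.4 ± 1.65 to 1.05 ± 0.386 CPM. Rgs16, a regulator of G protein signalling, rose from 1.95 ± 0.464 to 14.6 ± 2.33 CPM and the pseudokinase gene Trib2 from 2.06 ± 0.0999 to 14.1 ± 0.630 CPM. In all, 5281 of 12538 genes passed an adjusted p of 0.05 in this comparison, 2613 higher and 2668 lower, with a median absolute log2 change of 0.31. Of these 532 differed by at least 2-fold, 196 higher and 336 lower. By DESeq2 3100 genes passed.

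The camera test, adjusted over the 25 lists with at least 3 tested members, called 10 lists in this comparison. Upward calls had adjusted p = 1.47e-34 for MAPK output, 6.6e-06 for EGFR ligands, 2.23e-05 for AP-1, 5.61e-05 for proliferation, 0.00026 for hypoxia and 0.000247 for ATF4. Downward calls were made for basal keratinocyte genes (adjusted p = 7.93e-06), wound keratins (3.37e-06), squamous differentiation (0.00395) and YAP targets (0.0342). None held when the correlation between genes was estimated, a setting in which camera also uses only the 4 residual degrees of freedom. A lost call therefore need not come from correlation between genes. The values were adjusted p = 0.0886 with an estimated correlation for MAPK output, 0.127 for the basal and the wound lists, 0.138 for EGFR ligands, 0.216 for AP-1 and 0.33 for the other 5. Adjusted over the list alone, the counts of the called lists were the same except for AP-1, with 8 higher and 1 lower. The squamous median was -0.45 as fitted, -0.76 without NS Dox-4OHT replicate 2 and -0.02 with its 5 members at 3 or fewer counts set to their floor. The squamous call ended without the filter on low counts (adjusted p = 0.0752), as did that of YAP targets (0.278). The call of YAP targets also ended with only the 4 libraries compared (0.0521), and without NS DMSO replicate 2 or NS Dox-4OHT replicate 1. It ended as well without either knockdown DMSO library or knockdown Dox-4OHT replicate 2, which are outside this comparison. Without each of these 3 the list's median was -0.06, as without the filter on low counts, against -0.16 in the main fit. The filter was applied anew without each library, so a change in the members tested cannot be told apart from a difference between replicates.

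Lists that the test did not call in NS cells under Ras were Hedgehog targets (4 higher, 2 lower of 9; adjusted p = 0.0552), which mark the driver pathway of basal cell carcinoma, and hair follicle genes (4 and 6 of 12; 0.0565). Nor were interferon-stimulated genes called (0 and 8 of 15; 0.0565), or inflammatory cytokines (5 and 0 of 14; 0.0649). Each of these 4 passed without single libraries, in fits where the filter was applied anew and the members tested could differ. Hedgehog targets passed without NS DMSO replicate 1 (0.0338), either NS Dox-4OHT library (0.0468 and 0.0365) or knockdown Dox-4OHT replicate 1 (0.0497). Hair follicle genes passed without NS DMSO replicate 2 (0.0361), interferon-stimulated genes without NS DMSO replicate 2 (0.00623) or NS Dox-4OHT replicate 2 (0.000145). Inflammatory genes passed without NS DMSO replicate 1 (0.0338) or NS Dox-4OHT replicate 2 (0.0409). Without the filter on low counts, interferon-stimulated genes (0.00536), inflammatory genes (0.0329) and sterol biosynthesis genes (0.0366) passed. Hedgehog targets also passed with only the 4 libraries compared (0.0475), the replicate number as a block (0.0476) or length correction (0.0496), as did hair follicle genes with the block (0.0434) or without Rn45s (0.0485) and inflammatory genes with only the 4 libraries compared (0.0226). Hedgehog targets that rose included the cyclins Ccnd1 (0.68 ± 0.04) and Ccnd2 (0.45 ± 0.03). Gli1, a direct Hedgehog target picked after its values were seen, had a log2 change of -1.06 in NS cells (adjusted p = 0.0108) and -1.18 in knockdown cells (adjusted p = 0.0329). In NS cells its call ended without NS DMSO replicate 1 (log2 change -0.50, adjusted p = 0.391), without NS Dox-4OHT replicate 1 (0.0841) and with DESeq2 (0.173). In knockdown cells it ended without any one of the 4 knockdown libraries (0.0513 to 0.236) and with DESeq2 (0.189). In NS cells the hair follicle factor gene Dlx3 fell (-1.71 ± 0.10). TGF-beta and SMAD targets were divided, with 6 higher and 6 lower of 20 (adjusted p = 0.804). Thbs1 fell (-0.52 ± 0.03) and Bhlhe40 rose (1.02 ± 0.07). Receptors and SMADs of the TGF-beta family had 5 higher and 3 lower of 17 (0.715) and BMP targets 2 and 2 of 9 (0.817). Mesenchymal genes had 5 and 2 of 9 (0.188) and protease and invasion genes 5 and 7 of 15 (0.0712). For p53 targets the counts were 4 and 5 of 17 (0.232) and for sterol biosynthesis 10 and 4 of 21 (0.119; 11 and 4 adjusted over the list alone). For Wnt targets they were 3 and 2 of 6 (0.119) and for the Notch pathway 2 and 2 of 9 (0.232). Markers of fibroblasts had 1 higher and 0 lower member of 3 (0.418) and those of immune, endothelial and pigment cells 0 and 2 of 4 (0.281). Of the simple epithelial keratins, 2 were tested, too few for the list test. Krt19 had 12 counts in the NS libraries under DMSO (2.5 and 9.5) and 1 under Dox and 4OHT, a ratio of 10.6 (95% interval 1.57 to 453, counting error only). The ratio was 4.14 without NS DMSO replicate 2 and 18.0 without NS DMSO replicate 1.

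The knockdown effect under DMSO addresses what loss of the TGF-beta receptor changed without Dox and 4OHT. Genes of the cornified envelope, the outer shell of terminally differentiated keratinocytes, were higher in knockdown cells: Sprr1b, 1 of a family of similar genes whose reads may be shared, went from 3.28 ± 0.590 to 80.9 ± 0.674 CPM and loricrin (Lor) from 2.52 ± 0.0496 to 58.5 ± 4.79 CPM. The adhesion molecule gene Icam1, an NF-kB target, rose from 2.99 ± 0.188 to 51.2 ± 1.05 CPM and the neutrophil chemokine gene Cxcl1 rose by 3.08 ± 0.18 on the log2 scale. Etv4 and Etv5 were higher by 3.09 ± 0.07 and 3.77 ± 0.12 on the log2 scale in the absence of Dox and 4OHT. Hmga2, a chromatin protein gene of embryonic and tumour cells, rose by 5.60 ± 0.13 (adjusted p = 2.07e-23). The collagen gene Col11a1, by contrast, fell from 122 ± 6.36 to 1.01 ± 0.562 CPM and the fibrillin gene Fbn2 from 224 ± 40.7 to 9.50 ± 0.476 CPM.

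Squamous terminal differentiation genes counted 14 higher and 4 lower of 21 under DMSO, with Dmkn among those that fell (-1.40 ± 0.06). The median level of the 21 was low, at 1.63 CPM in NS and 3.86 CPM in knockdown cells. Of the MAPK output genes 16 of 17 rose and none fell, and of the EGFR ligands 6 of 7 rose, Epgn by 2.19 ± 0.09 and Tgfa by 1.37 ± 0.06. Inflammatory genes rose in 11 of 14 cases, the macrophage growth factor Csf1 by 1.94 ± 0.09. By contrast 12 of 15 interferon-stimulated genes fell and none rose, Irf9 changing by -2.79 ± 0.17 and Usp18 by -3.07 ± 0.34. TGF-beta and SMAD targets were 9 lower and 6 higher of 20. The feedback gene Pmepa1 (-1.33 ± 0.04), Thbs1 (-0.91 ± 0.03) and the basement membrane collagen gene Col4a1 (-0.87 ± 0.03) fell. Hair follicle genes were 8 lower and 3 higher of 12, with Dlx3 at -1.65 ± 0.10 and Nfatc1 at -1.44 ± 0.09. Among mesenchymal genes (4 lower, 2 higher of 9) the cadherins Cdh2 and Cdh11 fell (-1.59 ± 0.04 and -1.55 ± 0.11). Protease and invasion genes were 7 higher and 6 lower of 15. The urokinase gene Plau rose (1.20 ± 0.06), as did Pdpn, which encodes a membrane glycoprotein and not a protease (1.19 ± 0.04). Wound keratins were 3 lower and 1 higher of 6, Krt16 and Krt6a at -2.29 ± 0.07 and -0.70 ± 0.03, with the same doubt over shared reads as in the Ras response.

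Several genes were almost absent from the NS libraries under DMSO, and their ratios carry wide 95% intervals for counting error alone. Calm4, a calmodulin-like gene of keratinocytes, had 2 counts there and 466 in knockdown cells, a ratio of 257 (70.8 to 2130). Padi4, a protein arginine deiminase gene, had a ratio of 193 (53.1 to 1601) and the protocadherin gene Pcdh17 one of 211 (58.0 to 1747). Mycn, a Hedgehog target, had no counts in the NS libraries and 86 in knockdown cells, and was at least 31.6-fold higher with the floor of 3 counts taken over the group. Among the 2 tested simple epithelial keratins both rose. The log2 change of Krt19 was 3.04 with both NS DMSO libraries and 4.65 without replicate 2 of them, and that of Krt7 3.45 and 7.44.

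In this comparison 7763 genes passed the test, 3877 higher and 3886 lower, and 1342 differed by at least 2-fold, 517 higher and 825 lower. The median absolute log2 change of the genes that passed was 0.41. The list test called 10 lists: upward MAPK output (adjusted p = 1.29e-15), inflammatory genes (1.15e-07), EGFR ligands (4.85e-07), squamous differentiation (3.64e-06) and proteases (0.00594). The downward calls were interferon-stimulated genes (adjusted p = 0.00594), hair follicle genes (0.0078), wound keratins (0.0285), TGF-beta targets (0.0354) and mesenchymal genes (0.0454). None held when the correlation was estimated, with adjusted p = 0.216 with an estimated correlation for MAPK output, EGFR ligands and inflammatory genes, 0.376 for interferon-stimulated genes and 0.314 for the other 6. Adjusted over the list alone, inflammatory genes had 12 higher members and interferon-stimulated genes 1 higher beside 12 lower, the other called lists being unchanged. The protease list was called upward with a median of -0.01 and a mean of 0.46. Its median lay between -0.05 without NS DMSO replicate 2 and 0.04 without NS DMSO replicate 1. Without the filter on low counts the calls of TGF-beta targets (adjusted p = 0.196), wound keratins (0.235), mesenchymal genes (0.285) and proteases (0.491) ended. That of mesenchymal genes also ended with the replicate number as a block (0.0535). It ended as well without NS DMSO replicate 1, knockdown DMSO replicate 1, NS Dox-4OHT replicate 1 or knockdown Dox-4OHT replicate 2. The Dox-4OHT libraries are outside this comparison, and the filter was applied anew without each library. The other 15 lists had adjusted p from 0.0526 for ATF4 to 0.98 for TGF-beta family receptors. ATF4 passed without NS DMSO replicate 1 (0.0303) or either knockdown Dox-4OHT library (0.0364 and 0.0401), with only the 4 libraries compared (0.0467) and with upper quartile scaling or length correction (both 0.0499). Median, mean and test differed in sign for Hedgehog targets (median -0.12, mean 0.52 as fitted and 0.13 with Mycn at its floor, test downward), TGF-beta family receptors (-0.06, 0.18 or 0.10 with 1 member at its floor, upward), p53 targets (0.05, 0.03, downward) and YAP targets (-0.05, 0.10, upward). Adjusted over the list alone, the uncalled TGF-beta family receptors had 7 higher and 7 lower members (6 and 7 over all genes). ATF4 had 5 and 9 (5 and 8) and the Notch pathway 5 and 2 (4 and 1). Immune, endothelial and pigment markers were lower in 4 of 4 members (adjusted p = 0.119), with Pecam1 at -0.45 ± 0.07.

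The third comparison, Dox and 4OHT against DMSO in knockdown cells, addresses the Ras response with little Tgfbr1. Glycolytic and hypoxia-induced genes rose together: Ldha went from 534 ± 17.1 to 910.2 ± 20.8 CPM, Aldoa rose by 1.12 ± 0.04 on the log2 scale and the hypoxia marker Ndrg1 by 1.82 ± 0.06. Inflammatory genes also rose, Cxcl1 by 1.88 ± 0.09 on the log2 scale and Icam1 from 51.2 ± 1.05 to 95.7 ± 2.13 CPM. Subunits of the replication helicase fell, with Mcm2 at -0.47 ± 0.04 and Mcm4 at -0.41 ± 0.04, while Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 0.80 ± 0.06 (adjusted p = 1.26e-10). The tight junction gene Cldn4 rose from 39.7 ± 0.939 to 266 ± 0.246 CPM and Txnip, which is induced by glucose, fell from 110.3 ± 6.55 to 34.6 ± 5.26 CPM.

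All 15 measured hypoxia and glycolysis genes and all 10 AP-1 subunits rose in knockdown cells under Ras, with Atf3 at 2.12 ± 0.09 and Jund at 0.55 ± 0.04. Inflammatory genes rose in 13 of 14 cases, Nfkbia, which encodes an NF-kB inhibitor, by 0.78 ± 0.05. MAPK output genes had 14 higher and 2 lower of 17: Ier3 rose by 1.94 ± 0.05 and Etv5 went from 44.2 ± 5.68 to 105 ± 5.48 CPM, while Egr1 fell (-1.30 ± 0.08). ATF4 genes had 12 higher and 2 lower of 16, Ddit4 rising by 1.49 ± 0.06. Sterol biosynthesis genes had 14 and 3 of 21, Msmo1 rising by 0.41 ± 0.04. Proliferation genes were lower in 17 of 23 cases and higher in none. Protease and invasion genes rose in 10 of 15 cases and fell in none, among them Hmga2, a chromatin protein gene (0.81 ± 0.06), and the integrin gene Itga5 (0.88 ± 0.07). The p53 targets were 8 higher and 1 lower of 17. Among basal keratinocyte genes 8 of 13 fell and 3 rose, Krt14 at -0.63 ± 0.03 and Krt5 at -0.54 ± 0.03. Receptors and SMADs of the TGF-beta family had 8 higher and 1 lower of 17, with Smad1 at 0.73 ± 0.06 and the co-receptor gene Tgfbr3 at 2.35 ± 0.24. Squamous differentiation genes were divided, with 6 higher and 10 lower of 21, or 12 lower adjusted over the list alone. Sprr1b rose (1.22 ± 0.05), as did Grhl3, a regulator of the epidermal barrier (1.49 ± 0.09), and Lor fell (-0.95 ± 0.08). EGFR ligands had 3 higher of 7 (adjusted p = 0.45). Of the wound keratins none passed, Krt6a being at 0.04 ± 0.03 (adjusted p = 0.429) and Krt16 at -0.05 ± 0.08 (adjusted p = 0.672), and neither simple keratin passed.

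Of the genes tested, 4531 passed in knockdown cells under Ras, 2446 higher and 2085 lower (54.0% higher, but 47.9% with upper quartile scaling), with a median absolute log2 change of 0.30. Of these 335 differed by at least 2-fold, 249 higher and 86 lower. DESeq2 gave 2476 genes. The list test called 12 lists, upward for hypoxia (adjusted p = 1.16e-42), inflammatory genes (5.25e-23), MAPK output and AP-1 (both 2.15e-13) and ATF4 (3.9e-11). Also upward were proteases (adjusted p = 6.39e-05), sterol biosynthesis (0.00126), p53 targets (0.00805), TGF-beta family receptors (0.0243) and immune, endothelial and pigment markers (0.0212), and downward proliferation (8.23e-09) and basal keratinocyte genes (0.0212). Hypoxia and inflammatory genes held with adjusted p = 0.0267 with an estimated correlation. The others did not, with AP-1 and proteases at 0.0659, MAPK output at 0.075, ATF4 at 0.106 and p53 at 0.145. On the same terms the immune, endothelial and pigment markers were at 0.175, proliferation at 0.211, sterol biosynthesis at 0.222, basal genes at 0.227 and the receptors at 0.286. Adjusted over the list alone, proliferation had 18 lower members, sterol biosynthesis 15 higher, proteases 1 lower beside 10 higher and the receptors 2 lower beside 8 higher, the other called lists being unchanged. The call of basal genes ended without knockdown Dox-4OHT replicate 2 (adjusted p = 0.0569) and that of the receptors when a trend with gene length was removed (0.0519). The other 13 lists had adjusted p from 0.136 for Wnt targets to 0.981 for wound keratins and fibroblast markers. Wnt targets passed without knockdown Dox-4OHT replicate 1 (0.0408), and squamous genes (0.306) passed downward without knockdown DMSO replicate 2 (0.000257). Without the filter on low counts, Wnt targets (0.0255), squamous genes (0.0315) and interferon-stimulated genes (0.0486) passed. Median, mean and test differed in sign for 5 uncalled lists: Hedgehog targets (median 0.13, mean -0.12, test upward), wound keratins (0.10, 0.32, downward), YAP targets (0.09, -0.02, downward), the Notch pathway (0.01, -0.09, downward) and fibroblast markers (0.19, -0.35, downward). Among the markers of other cell types, Cd68, a lysosomal protein gene of macrophages, rose from 4.71 ± 0.292 to 15.2 ± 0.464 CPM.

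The knockdown effect under Dox and 4OHT addresses what loss of the receptor changed in cells with active Ras. Squamous and inflammatory genes were also higher here in knockdown cells: Sprr1b was at 5.22 ± 0.0349 CPM in NS and 189 ± 2.54 CPM in knockdown cells, Icam1 at 3.70 ± 0.669 and 95.7 ± 2.13 CPM and Cxcl1 at 3.98 ± 0.171 and 47.8 ± 3.62 CPM. Msln, which encodes the surface protein mesothelin, was higher by 5.91 ± 0.18 on the log2 scale (adjusted p = 1.21e-20), and the secreted protease gene Plau and its inhibitor Serpinb2 by 2.06 ± 0.07 and 3.56 ± 0.10. Genes of cell division were lower: the ribonucleotide reductase gene Rrm2 had a change of -1.31 ± 0.04, the mitotic activator gene Cdc20 of -0.94 ± 0.04 and the cyclin gene Ccna2 of -0.85 ± 0.04. Col11a1 fell from 43.5 ± 4.81 to 0.931 ± 0.120 CPM and Cyp4b1, a cytochrome P450 gene, from 20.4 ± 2.57 to 0.358 ± 0.0460 CPM.

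Of 21 squamous differentiation genes 17 were higher and 1 lower in knockdown cells, with Lor at 3.61 ± 0.14 and Grhl3 at 2.59 ± 0.11. The median level of the 21 was 0.791 CPM in NS and 4.30 CPM in knockdown cells. Inflammatory genes rose in 12 of 14 cases, and protease and invasion genes were 11 higher and 4 lower of 15. Proliferation genes had 19 lower and 1 higher of 23. Hypoxia genes had 11 higher and 1 lower of 15, the oxygen sensor gene Egln3 at 2.08 ± 0.08. MAPK output genes rose in 13 of 17 cases and fell in none, Ier3 by 2.41 ± 0.05 and Etv5 by 0.77 ± 0.06. Of the EGFR ligands 4 of 7 rose, Tgfa by 0.91 ± 0.06. Mesenchymal genes were 6 lower and 2 higher of 9, with Cdh2 at -1.58 ± 0.04 and the repressor gene Zeb1 at -2.53 ± 0.20. TGF-beta and SMAD targets had 7 higher and 8 lower of 20 (adjusted p = 0.302; 8 and 8 adjusted over the list alone). The targets Pmepa1 (-1.20 ± 0.04), Thbs1 (-0.98 ± 0.03) and Col4a1 (-0.72 ± 0.03) fell. BMP targets were 4 higher and 5 lower of 9, Id4 at -3.22 ± 0.17 and Bambi at -2.55 ± 0.19, without a list call (adjusted p = 0.518). The Notch receptor gene Notch3 was higher by 2.10 ± 0.16 and the receptor gene Tgfbr2, the partner of Tgfbr1, by 0.92 ± 0.04. Crct1, of the cornified envelope, and the imprinted RNA gene H19 each had 1 count in the NS libraries under Dox and 4OHT. Their ratios were 328 (95% interval 58.3 to 12957, counting error only) and 280.3 (49.8 to 11090). The simple keratin Krt19 had 1 count there and a ratio of 92.2 (16.2 to 3696), and Krt7, with none, was at least 13.7-fold higher.

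Under Dox and 4OHT 7542 genes passed, 3824 higher and 3718 lower in knockdown cells (50.7% higher, but 46.3% with upper quartile scaling and 49.3% without Rn45s), with a median absolute log2 change of 0.42. Of these 1290 differed by at least 2-fold, 704 higher and 586 lower. The list test called 8 lists, upward for inflammatory genes (adjusted p = 7.37e-21), proteases (4.36e-11), squamous differentiation (2.56e-10), hypoxia (8.35e-06), MAPK output (0.000101) and EGFR ligands (0.0195). The downward calls were proliferation (adjusted p = 1.59e-06) and mesenchymal genes (0.00423). Inflammatory genes and proteases held, with adjusted p = 0.0417 with an estimated correlation for both, whereas squamous and mesenchymal genes were at 0.24 and the other 4 at 0.318. Adjusted over the list alone, squamous genes had 2 lower members and hypoxia genes 12 higher, the other called lists being unchanged. The squamous median was 2.54 as fitted and 2.30 with its 5 members at 3 or fewer counts set to their floor. The call of mesenchymal genes ended without the filter on low counts (adjusted p = 0.139). Their median was -0.28 with all libraries, -1.46 without NS Dox-4OHT replicate 1 and -0.64 without knockdown Dox-4OHT replicate 1. It also moved without libraries outside this comparison, to -1.32 without knockdown DMSO replicate 1 and -0.80 without NS DMSO replicate 2. As the filter was applied anew each time, a change in the members tested cannot be told apart from a difference between replicates. The other 17 lists had adjusted p from 0.0934 for p53 targets to 0.764 for sterol biosynthesis. Median, mean and test differed in sign for Hedgehog targets (median -0.39, mean 0.05 as fitted but below 0 with 1 member at its floor, test downward), TGF-beta targets (0.02, 0.02, downward) and sterol biosynthesis, whose median was below 0 and whose mean was 0.03.

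**Figure D2:**
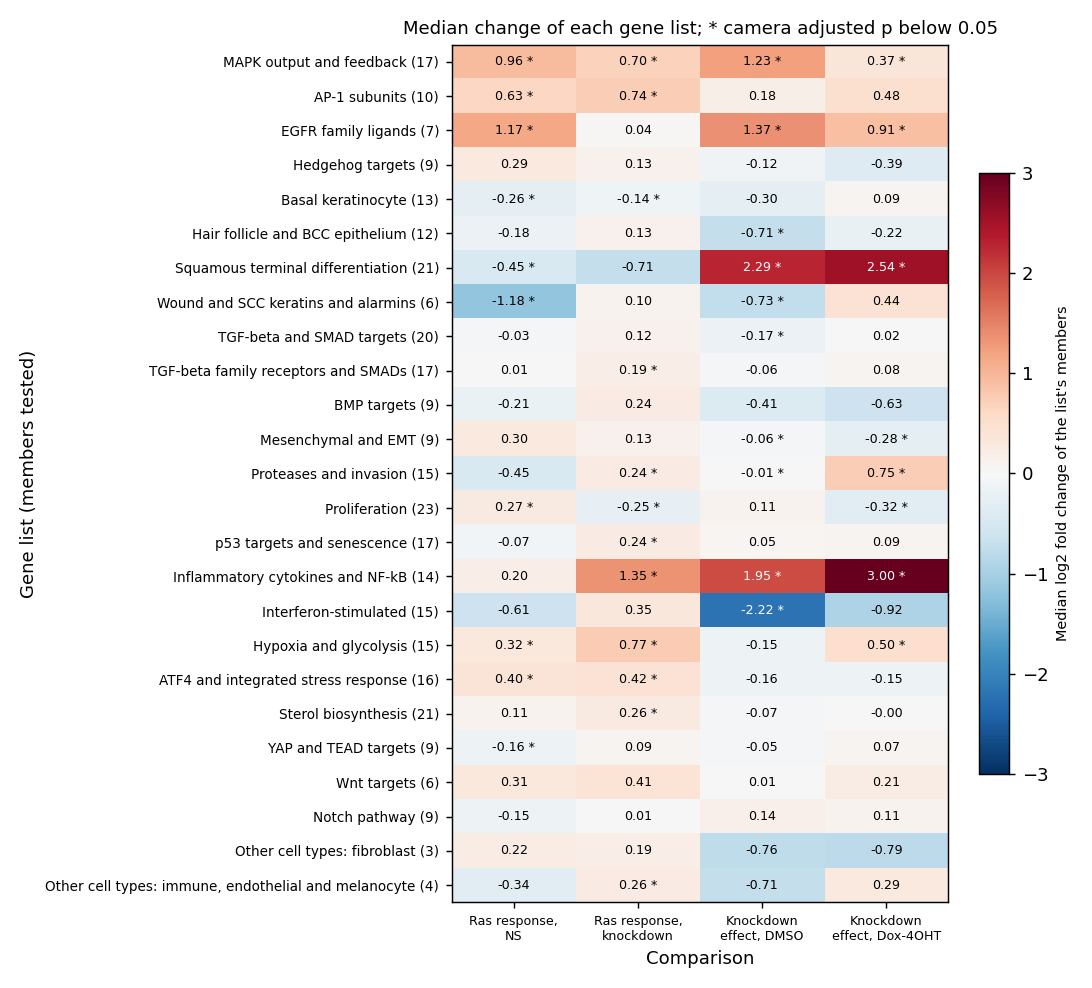
Median log2 fold change of the tested members of 25 gene lists (vertical axis, members tested in brackets) in 4 comparisons (horizontal axis), red for higher and blue for lower, with a star where camera gave an adjusted p below 0.05. Squamous differentiation has medians of 2.29 and 2.54 for the knockdown effect under DMSO and under Dox and 4OHT. Medians are of fitted values, and with members at 3 or fewer counts at their floor the latter is 2.30 and that of the Ras response in NS cells is -0.02 in place of -0.45 (-0.76 without NS Dox-4OHT replicate 2). For mesenchymal genes the median of the knockdown effect under Dox and 4OHT is -0.28, and -1.46 without NS Dox-4OHT replicate 1. It is -1.32 without knockdown DMSO replicate 1, which is outside this comparison, and the members tested can change when a library is left out.

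Comparisons that share no library were set beside each other to ask how far the same genes answered. For the Ras responses in NS and in knockdown cells, 827 genes were higher in both (509.8 by chance for independent lists), 549 lower in both (444 by chance) and 1056 opposite (955 by chance). Thus 56.6% of the genes called in both had the same direction. Across genes the correlation of the log2 changes was 0.292. For the knockdown effects under the 2 treatments, 2415 genes were higher in both (1182 by chance), 2281 lower in both (1152 by chance) and 733 opposite (2335 by chance), with 86.5% in the same direction and a correlation of 0.760. By DESeq2 727 genes in place of 1376 had the same direction in both Ras responses, and at an adjusted p of 0.01 917 did.

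The interaction of Ras and knockdown tests whether the Ras response differed between NS and knockdown cells. Etv4 rose with Ras from 11.2 ± 0.776 to 119 ± 7.20 CPM in NS cells and from 95.2 ± 5.16 to 154 ± 2.89 CPM in knockdown cells, so that the log2 difference of its responses was -2.72 ± 0.09 (adjusted p = 9.2e-18). That of Etv5 was -2.99 ± 0.15. Mcm2 rose in NS cells, from 242 ± 10.1 to 289 ± 7.20 CPM, and fell in knockdown cells, from 353 ± 7.36 to 254 ± 6.66 CPM (difference -0.73 ± 0.05, adjusted p = 2.63e-11). Cdkn1a went the opposite way, falling from 50.5 ± 1.72 to 31.1 ± 1.13 CPM in NS cells and rising from 39.5 ± 3.78 to 68.7 ± 1.64 CPM in knockdown cells (difference 1.51 ± 0.10). The keratin gene Krt16 fell with Ras in NS cells and did not pass in knockdown cells, where it started at 71.8 ± 8.52 CPM against 349.8 ± 20.6 CPM in NS cells (difference 2.68 ± 0.11).

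MAPK output genes had a lower Ras response in knockdown cells for 12 of 17 members and a higher one for 2, Ier3 among them (1.23 ± 0.08). EGFR ligands had a lower one for 6 of 7, Epgn at -1.16 ± 0.12. Proliferation genes responded lower for 20 of 23 members and higher for none. Responses were higher in knockdown cells for 13 of 15 hypoxia genes, with Ndrg1 at 1.56 ± 0.09, and lower for none. They were higher for 8 of 15 protease and invasion genes and lower for 3, with the laminin chain gene Lamb3 at 0.72 ± 0.05. They were also higher for 7 of 17 p53 targets and lower for 1. Camera also called basal keratinocyte genes (7 higher, 2 lower of 13), hair follicle genes (6 and 1 of 12), and wound keratins (2 and 1 of 6), calls that were lost at adjusted p = 0.256, 0.336 and 0.109 with an estimated correlation. It called interferon-stimulated genes (7 and 0 of 15) and immune, endothelial and pigment markers (3 and 0 of 4) as well, lost at adjusted p = 0.419 and 0.109 with an estimated correlation. Krt14 and Krt5 had differences of 0.60 ± 0.04 and 0.63 ± 0.05, Dlx3 of 2.06 ± 0.16, the interferon signalling gene Stat2 of 0.71 ± 0.13 and Cd68 of 1.79 ± 0.20. Of the 196 genes at least 2-fold higher with Ras in NS cells, 91 had an interaction against that direction and 7 with it. Their median log2 response was 1.49 in NS and 0.70 in knockdown cells. Of the 336 at least 2-fold lower, 219 had an interaction against and 1 with it, and the medians were -1.45 and -0.17. Genes picked for a large response in NS cells tend to lie nearer 0 in any other comparison.

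The interaction passed for 4791 genes, 2530 with a higher and 2261 with a lower response in knockdown cells (52.8% higher, but 49.9% with upper quartile scaling), 537 of them by at least 2-fold (442 and 95), and DESeq2 gave 2694. The list test called 11 lists: downward proliferation (adjusted p = 1.02e-15), MAPK output (1.77e-13) and EGFR ligands (5.32e-05). The upward calls were hypoxia (adjusted p = 3.29e-11), wound keratins (2.11e-05), proteases (5.35e-05), p53 targets (0.00273), immune, endothelial and pigment markers (0.00571), hair follicle genes (0.00845), interferon-stimulated genes (0.0147) and basal keratinocyte genes (0.0213). None held, with adjusted p = 0.109 with an estimated correlation for 8 of them, 0.336 for hair follicle, 0.419 for interferon-stimulated and 0.256 for basal genes. Adjusted over the list alone, proliferation had 21 lower members, wound keratins 4 higher, proteases 9, p53 targets 9, interferon-stimulated genes 8 and basal genes 8, the other called lists being unchanged. The other 14 lists had adjusted p from 0.0558 for inflammatory genes to 0.877 for the Notch pathway. Inflammatory genes passed without NS DMSO replicate 2 (0.0313), either knockdown DMSO library (0.0259 and 0.00452), NS Dox-4OHT replicate 1 (0.0294) or knockdown Dox-4OHT replicate 1 (0.042), and with upper quartile scaling (0.0446). YAP targets passed with length correction (0.0475). Squamous genes (0.0986) passed without NS DMSO replicate 1 (0.0389) or knockdown DMSO replicate 1 (0.0255), and ATF4 genes (0.14) without NS Dox-4OHT replicate 2 (0.0466). Signs differed for AP-1 (median 0.12, mean -0.06, test upward), ATF4 (-0.11, 0.20, upward), Wnt targets (0.24, 0.11, downward) and the Notch pathway (-0.02, 0.02, upward).

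**Figure D3:**
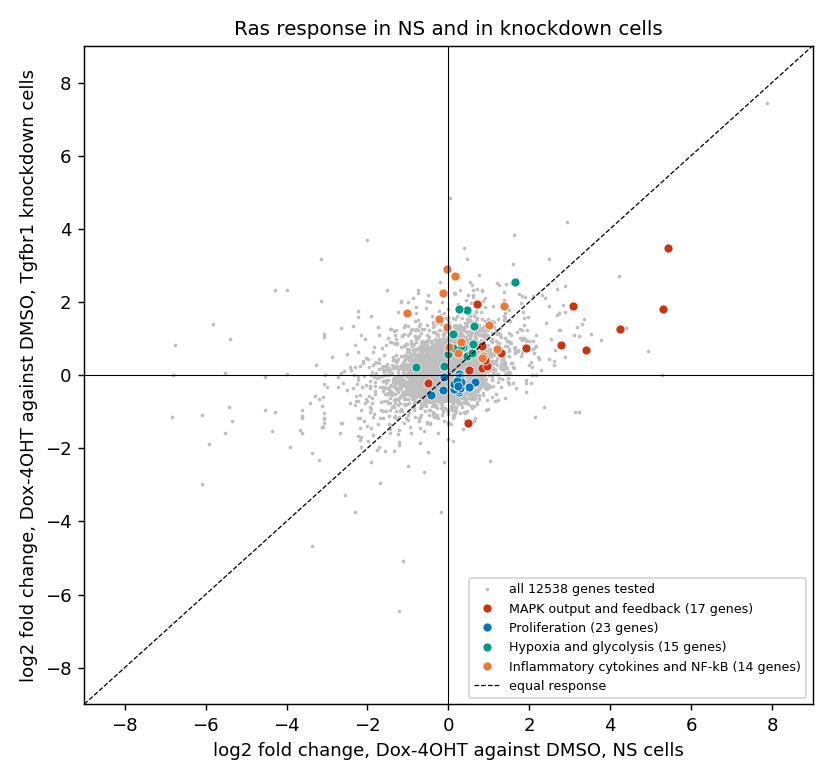
Log2 fold change of Dox and 4OHT against DMSO in NS cells (horizontal axis) and in knockdown cells (vertical axis) for 12538 genes in grey, with the MAPK output, proliferation, hypoxia and inflammatory lists in colour and a dashed line where both responses are equal. All but 1 of the proliferation genes lie below the line, 20 of 23 past the interaction test, and hypoxia genes above it, 13 of 15 past the test.

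**Figure D4:**
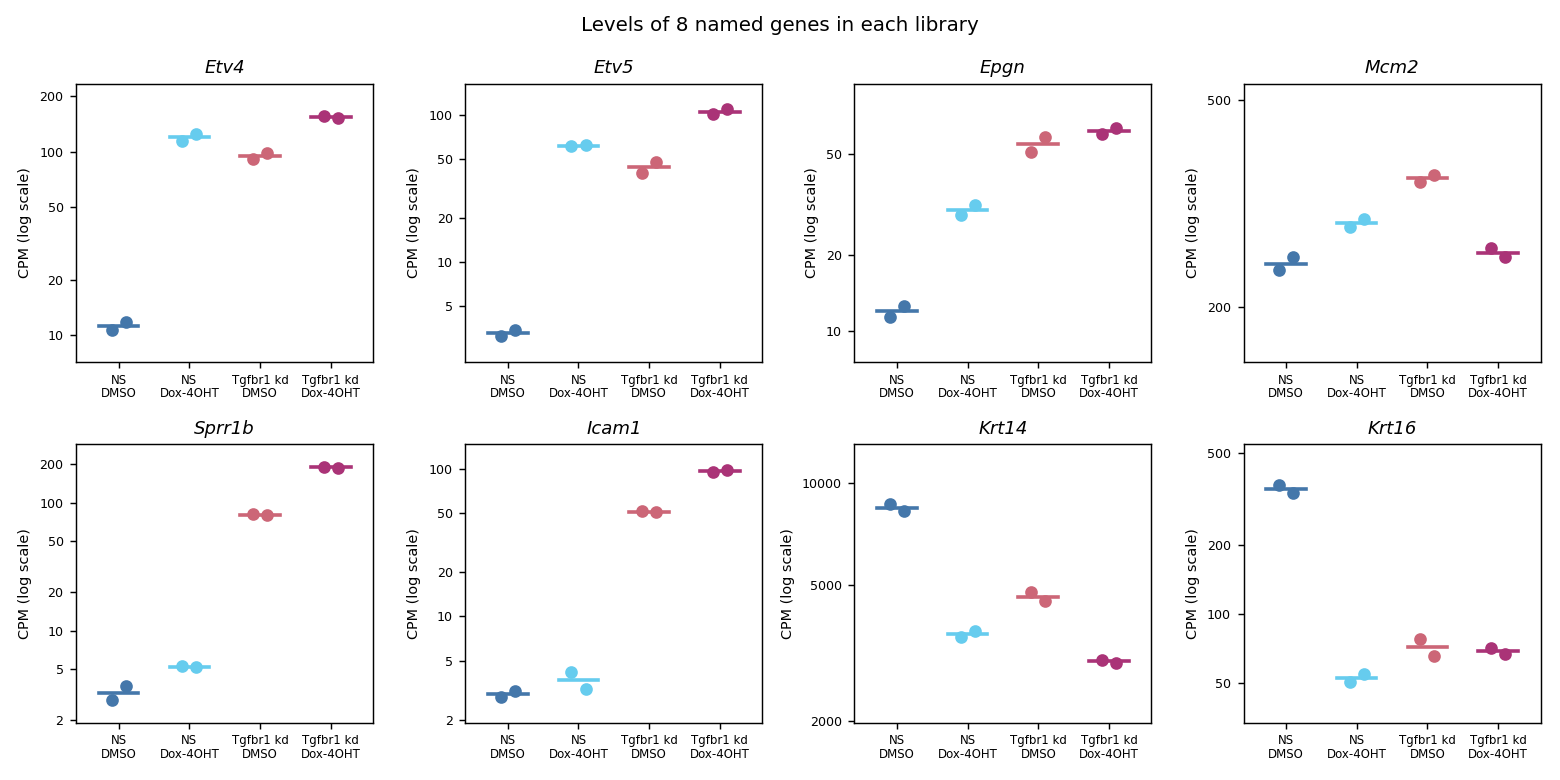
Levels of Etv4, Etv5, Epgn, Mcm2, Sprr1b, Icam1, Krt14 and Krt16 in CPM on log axes, with 1 point per library and a line at the mean of the 2 libraries of each group. Etv4 and Etv5 start higher in knockdown cells under DMSO, at 95.2 and 44.2 CPM against 11.2 and 3.26 CPM in NS cells, and Sprr1b and Icam1 are higher in all 4 knockdown libraries.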

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

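The tests of Esr1 and of the starting level, the medians with members at their floor, length correction, and upper quartile scaling of lists were chosen after the result was seen; the other tests given here were not. The results below differed between NS and knockdown cells by the interaction test of edgeR (genes) or camera (lists), which compares the Ras response of the 2 lines. The interaction passed for 4791 genes.

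MAPK output and feedback genes had a median interaction of -0.71 on the log2 scale (-0.70 with members at 3 or fewer counts at their floor). Spry4 was at -3.48, Etv5 at -2.99 and Etv4 at -2.72, while Ier3, against the direction of most members, was at 1.23. The list call of camera was lost at an adjusted p = 0.109 with an estimated correlation. The tables argue against scaling between libraries as the whole cause: over RLE, upper quartile and length-corrected scaling the median was at most -0.701, with 12 of 17 members smaller each time, while hypoxia genes moved up in the same contrast. The interaction is the difference of the knockdown effects under the 2 treatments, so a smaller response goes with a higher start or a lower end in knockdown cells. Of the 12 members with a smaller response 12 were called higher under DMSO and not lower under Dox and 4OHT, which places the difference at the start without explaining it. Under DMSO 16 of all 17 members were called higher and 0 lower, so a higher start is not particular to these 12. Esr1 was higher by 0.129 in knockdown than in NS cells under Dox and 4OHT, which goes against less transgene in the knockdown line if the induced Esr1 counts come from the transgene, and that explanation stays open because their origin is not known. Under DMSO Esr1 was also higher in knockdown than in NS cells, by 0.586 ± 0.062, so the 2 lines differed in it without induction. Whether Ras was active under DMSO was not measured. Whether the receptor itself or a difference between the 2 lines raised the starting level stays open too, with 1 shRNA per arm.

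The median interaction of other lists was -1.13 for EGFR ligands, -0.44 for proliferation, 0.14 for basal keratinocyte genes, 0.50 for proteases and invasion, 0.31 for p53 targets, 0.59 for hypoxia and glycolysis, 1.02 for wound keratins and alarmins and 0.86 for immune, endothelial and pigment markers. That of hair follicle genes was 0.39 with all libraries and 0.23 without knockdown Dox-4OHT replicate 1, and that of interferon-stimulated genes was 1.02 with all libraries, 0.66 without NS DMSO replicate 1, 0.64 without NS Dox-4OHT replicate 1 and 0.88 with members at 3 or fewer counts at their floor. None of these list calls held with an estimated correlation.

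Of the genes with the largest interaction, the metalloprotease gene Adam8 was at 2.97, Nipal1 at 2.84, Krt16 at 2.68, the forkhead gene Foxq1 at 2.66 and Pgm5 at 2.63, and on the other side Fxyd5 was at -3.11 with all libraries and at -7.08 without NS DMSO replicate 1. EGFR ligands had Epgn at -1.16, Nrg1 at -0.99 and Ereg at -1.44, and the Wnt target Tcf7 was at -2.03. Among the keratinocyte genes Lama3 was at 0.80, Krt14 at 0.60, Krt5 at 0.63, Krt17 at 0.77, Dlx3 at 2.06, Msx2 at 1.17, Krt6a at 1.06, Lamb3 at 0.72 and Serpinb2 at 2.14, the keratins with the doubt over shared reads. Proliferation genes had Mcm2 at -0.73, Mcm5 at -0.63 and Mcm4 at -0.66, and p53 targets Cdkn1a at 1.51, Perp at 0.59 and Pmaip1 at 0.56. Interferon-stimulated genes had Stat2 at 0.71, Ifit1 at 2.39 and Ddx58 at 1.42, hypoxia genes Ndrg1 at 1.56, Aldoa at 1.01 and Pfkl at 0.47, and the markers of other cell types Cd68 at 1.79 and Pecam1 at 0.92.

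The interaction of 3 further genes lay near the threshold, and its call ended without several libraries in turn while the value moved by less than 1.5 times. Nras, at -0.13, no longer passed without NS DMSO replicate 1 (adjusted p = 0.0925) or 2 (0.0858), knockdown DMSO replicate 2 (0.158), NS Dox-4OHT replicate 1 (0.0979) or knockdown Dox-4OHT replicate 1 (0.0832) or 2 (0.12), by edgeR with Benjamini-Hochberg adjustment, nor with RLE scaling (0.0562), length correction (0.0535) or DESeq2 (0.22). The protease inhibitor gene Slpi, at -1.79, no longer passed without NS DMSO replicate 1 (0.223), knockdown DMSO replicate 2 (0.0929), NS Dox-4OHT replicate 1 (0.0835) or knockdown Dox-4OHT replicate 1 (0.0546) or 2 (0.055). The pigment gene Pmel, at 0.81, no longer passed without knockdown DMSO replicate 2 (0.0896), NS Dox-4OHT replicate 1 (0.0626) or knockdown Dox-4OHT replicate 2 (0.0581), nor with DESeq2 (0.167).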

How the results depend on the processing

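Removal of the gene length trend, the counts without Rn45s, and several settings for lists, overlaps and named genes, among them lists without the filter on low counts, were chosen after seeing the data; the other settings were not. Over 8677 comparisons of 438 results for named genes with an alternative, 8350 kept direction and side of the threshold, 325 fell below it (221 under a required fold of 2, by construction), 2 rose above it and 0 reversed. Of 2350 such comparisons of 125 list results, 2194 kept both, 67 fell below (47 with an estimated correlation), 89 rose above (50 with fry) and 0 reversed. RLE, upper quartile and length-corrected scaling kept the numbers of called genes within 1.5 times, but with upper quartile factors the share of higher genes fell from 54.0% to 47.9% for Ras in knockdown cells, from 50.7% to 46.3% for the knockdown under Dox and 4OHT and from 52.8% to 49.9% for the interaction. These factors moved the median log2 change of all genes down as well, from 0.00280 to -0.0185, from -0.00713 to -0.0364 and from 0.0178 to 0.00250 in the same order. Why the factors differ was not tested. A fold of at least 2 left 532 genes for Ras in NS cells (36.8% higher, 49.5% without it), 1342 for the knockdown under DMSO (38.5% and 49.9%), 335 for Ras in knockdown cells (74.3% and 54.0%), 1290 for the knockdown under Dox and 4OHT (54.6% and 50.7%) and 537 for the interaction (82.3% and 52.8%), fewer by construction. DESeq2 called 3100 genes for Ras in NS cells (3078 of them shared with edgeR), 2476 for Ras in knockdown cells (2460 shared) and 2694 for the interaction (2674 shared), with 0 sign changes among the shared; the cause was not tested. The overlap of the Ras responses was 727 genes with DESeq2 (the cause was not tested) and 917 at an adjusted p of 0.01, a stricter threshold. Of the gene lists, 6 in place of 10 were called without the filter on low counts for the knockdown under DMSO; the cause was not tested. With an estimated correlation 0 were called for Ras in NS cells, 0 for the knockdown under DMSO and 2 for Ras in knockdown cells. The numbers were 2 for the knockdown under Dox and 4OHT and 0 for the interaction. This setting changes both the correlation and the degrees of freedom of camera (4 residual ones), and which of them ended the calls was not tested. Fry, which tests a list on its own and not against other genes, called 22 for Ras in NS cells, 20 for the knockdown under DMSO, 22 for the knockdown under Dox and 4OHT and 19 for the interaction, and its mixed test 25, 25, 23, 25 and 24 with Ras in knockdown cells in the third place. With the replicate number as a block, 5319, 7777, 4559, 7554 and 4814 genes were called in the order Ras in NS cells, knockdown under DMSO, Ras in knockdown cells, knockdown under Dox and 4OHT and interaction, and 12, 9, 12, 8 and 11 lists. The replicate block ended the call of mesenchymal genes under DMSO (camera adjusted p = 0.0535). For Ras in NS cells it made those of hair follicle genes (0.0434) and Hedgehog targets (0.0476). Deviations of libraries with the same number had correlations of -0.0227 to 0.0327 between groups. No deviation shared by number was thus seen, but whether the samples were set up in pairs is not known. The fits without single libraries, given next, applied the filter anew, so the genes and list members tested could differ. Without single libraries the counts of genes ranged from 3888 to 5329, 6650 to 7904, 3306 to 4670, 6585 to 7608 and 3918 to 4533 in the same order, the overlaps from 1099 to 1268 for Ras and 4253 to 4408 for the knockdown, and the lists from 9 to 13, 9 to 11, 11 to 13, 8 to 8 and 11 to 13, the lone library of a group being assumed to vary like the other groups. Depth limits the genes at a few counts, such as Krt19 and Krt7, whose knockdown effects under DMSO went from 3.04 to 4.65 and from 3.45 to 7.44 without NS DMSO replicate 2 and stayed past the threshold.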

Other observations

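The gene groups, the tests on Hras and its neighbours, the overlap of Ras in NS cells with the knockdown under DMSO, the split of the NS DMSO libraries and the choice of Igf2bp2, Igf2bp3, Hmga1, Thbs2, Cbfb, Rhbdd1, Mapre2 and Oaz1 came after values were seen, as did that of Hmga2, Cldn4, Msln and Txnip in comparisons for which the rule for named genes does not take them. Of 10 tested genes of the Hmga, Igf2bp and Lin28 families with H19 and Igf2, many of them known for high levels in embryonic tissue, 9 rose and 0 fell with the knockdown under DMSO and the same numbers under Dox and 4OHT, whether libraries were scaled by TMM, RLE or upper quartile factors. With TMM the exception was Lin28b, which passed under neither treatment (log2 changes of -0.148 ± 0.123 and -0.183 ± 0.141). Igf2 was near the floor, with a highest group mean of 1.59 CPM. The 10 include Hmga1b and Hmga2-ps1, near-identical copies of Hmga1 and Hmga2, so the same reads count more than once where the copies share them. Hmga2 rose by 5.60 and 4.25 on the log2 scale under the 2 treatments, Igf2bp2, which encodes an RNA-binding protein, by 2.14 and 1.81, Igf2bp3 by 1.21 and 0.90 and Hmga1, which may share reads with a near-identical copy, by 1.28 and 0.96. Of 21 keratin genes, not tested as a set and with the doubt over reads shared between near-identical members, 14 fell and 0 rose with Ras in NS cells, against 7 and 0 in knockdown cells, and 11 had a higher and 2 a lower response by the interaction test, with the same numbers under all 3 scalings. Under DMSO 11 of the 21 were already lower in knockdown than in NS cells and 6 higher, against 4 lower and 9 higher under Dox and 4OHT. A weaker fall with Ras can thus go with a lower start. The 7 tested S100a genes, of calcium-binding proteins, were all higher in knockdown than in NS cells under Dox and 4OHT under all 3 scalings, and 5 fell and 1 rose with Ras in NS cells. Of 11 Serpinb genes, of intracellular protease inhibitors, 8 were higher under Dox and 4OHT in knockdown cells and 0 lower (1 lower under upper quartile scaling). Of all 12538 genes tested, 3824 were higher in that comparison. Under DMSO only 3 of the 7 S100a genes were higher in knockdown cells and 0 lower, and 4 Serpinb genes were higher and 3 lower.

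The tight junction gene Cldn4 changed by 0.75 with Ras in NS cells and 2.75 in knockdown cells, and by 3.13 and 5.13 with the knockdown under DMSO and under Dox and 4OHT. Msln fell with Ras in NS cells (-2.26) and rose with the knockdown under both treatments (3.90 and 5.91), and Thbs2, which encodes a matrix protein, rose in all 4 comparisons (1.76 and 2.20 with Ras in NS and in knockdown cells, 1.58 and 2.02 with the knockdown). Txnip fell with Ras in both lines (-2.22 and -1.66). Several other genes fell in the knockdown line under both treatments: Cbfb, which encodes a subunit of the RUNX transcription factors, changed by -2.45 and -2.64, Rhbdd1, a membrane protease gene, by -2.57 and -2.22, Mapre2, a microtubule-binding protein gene, by -2.44 and -2.22, and Oaz1, which may share reads with a near-identical copy, by -1.86 and -1.66. Whether these differences follow the receptor or the line was not tested, with 1 shRNA per arm.

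Hras was lower in the 4 knockdown than in the 4 NS libraries, by a log2 difference near -1.6 under both treatments, so both with and without the RasV12 label. The tables argue against reads of an induced transgene counted at Hras, since its change with Dox and 4OHT in NS cells was -0.149. They argue as well against a loss of the chromosome region, since the 20 nearest tested genes, 10 on each side, had a median knockdown effect of -0.0563 (quartiles -0.165 and 0.141), with 6 lower and 6 higher. What stays open is a line difference that does not depend on induction, for which the knockdown effect on Hras differed by 0.00854 between the treatments, as 1 shRNA line per arm cannot part an effect of the receptor, an off-target effect of the shRNA on Hras or a difference between clones.

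Ras in NS cells and the knockdown under DMSO moved genes the same way: 1560 were higher in both (808 for independent lists), 1663 lower in both (827) and 728 opposite (1635), so that 81.6% of the genes called in both had the same direction. Both comparisons use the same NS DMSO libraries, and in 50 simulations with no effect these gave a median correlation of log2 changes of 0.479, against 0.346 observed. At most 2 genes were higher and 2 lower in both in these simulations. With no effect few genes can pass either test, so these counts do not bear on the observed ones. The tables argue against noise of the single shared libraries as the whole cause, since the covariance was 0.163 against 0.0102 to 0.0155 in the simulations. The difference from their median of 0.0120 was 0.151. With a different NS DMSO library in each comparison, so that none was shared, the covariance was 0.145 and 0.154 for the 2 ways to divide them, and 82.2% and 80.9% of the genes called in both had the same direction. Neither test covers a deviation common to both NS DMSO libraries, which was not simulated and stays in either division. Such a deviation cannot be told apart here from genes that answer both changes. Whether loss of the receptor and Ras reach these genes by the same path stays open as a hypothesis.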
